A study of Sus scrofa with 16 samples.

How the data were processed

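Single cells from the small intestine of 7.5-week-old mixed-breed female pigs were measured with droplet RNA sequencing (10x Chromium, 3' version 3 chemistry). Epithelium was released with dithiothreitol and EDTA, cleaned on Percoll, filtered and sequenced. The labels name 4 regions. DUOD was duodenum just past the pylorus, and JEJ was jejunum farther down. IPP was ileum containing Peyer's patches, the lymphoid follicles of the gut wall, and NoPP was ileum from areas without them.

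The deposited files hold, per the file headers, raw UMI counts (count) made with Cell Ranger 4, for 25880 genes and 6794880 listed barcodes per region. The submitters' notes give version 4.0.6. The genome build was not given in the sources used here, so no coordinates are printed. The labels list 16 titles, 4 per region, but there is 1 matrix per region and every barcode carries the same suffix, so no cell can be assigned to a title. A region was therefore treated as 1 sample. No test of a difference between regions was possible, and no p-value, standard error or number of changed genes is given. Of the 25880 genes, 17733 carried a symbol in the files, 977 took 1 from the gene name table, and 7170 stayed without.

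Barcodes were kept with at least 1000 UMIs, at least 500 genes and at most 25% of UMIs from the 13 mitochondrial genes. This left 718 barcodes in DUOD, 986 in JEJ, 3273 in IPP and 2205 in NoPP. Barcodes with at least 10 times as many UMIs in another library were left out, which took NoPP to 2084. Doublets were scored against 2 simulated doublets per cell. The automatic threshold called 26 of 7061 cells (0.368%), so it did not work. The highest scores were called instead, at 0.8% per 1000 kept cells, which removed 133 cells (1.88%). On simulated data this score called 33.7% of the 86 doublets added to IPP. Only 90 cells were called there, and doublets already in IPP competed for these calls. The share missed in the real data is therefore not known, and many doublets between cells of different types may remain. The final set held 714, 978, 3187 and 2049 cells in DUOD, JEJ, IPP and NoPP, 6928 in all.

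Counts were scaled to 10000 per cell and log-transformed. The 2000 most variable genes without the mitochondrial ones gave 30 principal components, and a shared-neighbour graph (20 neighbours) was clustered with the Leiden method at resolution 1. The 4 libraries were clustered together without integration. The 999 epithelial cells were then clustered again with 15 neighbours. Clusters were named from marker lists fixed before the data were examined. A marker counted when at least 10% of the cluster's cells had a UMI and its mean CPM (a gene's UMIs scaled to a common total) was 2-fold over a reference, the 10th percentile of clusters or, for epithelial classes, the non-epithelial cells. At least 3 markers were needed. The class with the most markers among the cluster's 10 leading genes was taken, and ties, also at 0 markers, went to the class with the highest mean log2 fold of its markers over the reference. Epithelial clusters 0, 4, 7 and 9, all enterocyte-like, had 0 markers among their leading genes and were named by this fold. Classes are written with the suffix "-like". Clusters with more markers of another class than of their own among the leading genes, or as many from 2 upward, stayed unnamed. The epithelial clusters were held only against the other epithelial classes in this, so cluster 9, with the red cell marker HBB and 0 enterocyte markers among its leading genes, kept its name. The naming rule was revised 3 times after the clusters had been seen, and only the markers were fixed in advance. It first took the highest mean z score of the markers, then their highest mean fold over the other cells, then the present rule with the 25th percentile as reference. On the final cells these versions gave the present class to 55.7, 93.4 and 100% of the DUOD cells. The first left 88.7% of the DUOD epithelial cells unnamed and the second left the crypt epithelial-like cells unnamed. The removal of shared barcodes, the doublet rate and the minimum of 10 cells for crypt-like and enterocyte-like comparisons were also chosen after seeing the data, and the clustering settings were set with the files at hand. The filters, the comparisons, the gene lists, the rule for named genes and the other settings, but for those named as chosen later, were fixed before the data were examined.

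Within a class, UMIs were summed over cells and divided by the class total, giving CPM. Regions were compared by the ratio of CPM with an exact 95% interval of a ratio of Poisson counts. Shares of cells have exact Clopper-Pearson 95% intervals. Where a count was 0, the limit given is 3 cells of the total in place of the Clopper-Pearson bound. Intervals and floors cover counting error only, not differences between pigs, tissue pieces or libraries. A gene with 0 UMIs in a region was set to 3 UMIs over that region's class, and its ratio is given as a bound. Classes other than crypt-like and enterocyte-like needed 30 cells in each region. In place of a test, genes were sorted by a size rule, at least 2-fold higher or lower. The rule was tried on simulated Poisson counts drawn from a single profile, without spread between cells. Their depths were those of JEJ and DUOD cells with a UMI of the epithelial gene EPCAM and none of the immune gene PTPRC (4630157 and 5988760 UMIs). The rule took in 100% of 4-fold shifts, 52% of 2-fold shifts and 0% of 1.5-fold shifts. It took in 0% of 5984 unshifted genes, and 95.8% of their intervals held the true ratio. Poisson draws fix this coverage in advance. Smaller classes, such as NoPP enterocyte-like cells with 513348 UMIs, were not simulated.

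The 19 gene lists fixed in advance were counted over members with at least 10 CPM in the higher region. They covered transport and digestion of carbohydrate, peptides, lipids, bile acids, minerals and vitamins, ion and water transport, xenobiotic metabolism, regional transcription factors, epithelial defence, interferon response, stress, proliferation, crypt stem cells, goblet secretion, hormones, T cell effectors, MHC class II presentation and the B cell follicle. A list's median log2 ratio was placed among 10000 random lists of equal size matched on expression. Percentiles were computed for every comparison, and only a few high ones are printed. On simulated data 9% of unshifted lists fell outside percentiles 2.5 to 97.5. Named genes have a symbol, are no mitochondrial, ribosomal, immunoglobulin or T cell receptor genes, and have at least 100 CPM in the higher region and 50 UMIs over both. Of these the 10 largest ratios each way were taken. List members with 50 CPM and a 2-fold ratio, the 2 highest members of each list and all hormones were added.

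Alternatives changed the UMI, gene and mitochondrial limits, the cell rule, the doublet step, the clustering, the scaling, the list minimum, the free RNA profile (barcodes with 1 to 100 UMIs) and the ileal library used. Leaving out a replicate was planned and could not be done. Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, scikit-image 0.26.0, igraph 0.11.9 and matplotlib 3.10.9.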

Results

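The study asked which epithelial cells make up the pig small intestine and how they differ along it. Droplet counts were available for 1 pooled sample each of duodenum (DUOD), jejunum (JEJ), ileum with Peyer's patches (IPP) and ileum without patches (NoPP). The 4 titles of each region could not be told apart, so there were no replicates and no difference was tested. All intervals are 95% and cover counting error only. The matrices held 91813234 UMIs in DUOD, 64364750 in JEJ, 65583520 in IPP and 44726845 in NoPP. After filtering, 714, 978, 3187 and 2049 cells remained in that order. Kept cells had a median of 3824, 3839.5, 4379 and 3608 UMIs and of 1324, 1388.5, 1494 and 1353 genes. Barcodes within the UMI, gene and mitochondrial limits, counted before doublets and shared barcodes were left out, held 8.74% of the UMIs of DUOD, 11.9% of JEJ, 34.2% of IPP and 22.1% of NoPP. Most barcodes above 1000 UMIs exceeded the mitochondrial limit.

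Epithelial cells made up 38.2% of the kept cells in DUOD (interval 34.7 to 41.9) and 33.5% in JEJ (30.6 to 36.6). The shares were 8.03% in IPP (7.11 to 9.03) and 6.93% in NoPP (5.87 to 8.12). T or innate lymphoid-like cells made up 55.9% in DUOD, 63.9% in JEJ, 49.8% in IPP and 84.5% in NoPP. B-like cells, which fill the follicles of Peyer's patches, were 34.4% of IPP (32.7 to 36.0) and 2.73% of NoPP (2.07 to 3.53). They were 1.02% of JEJ and 0.140% of DUOD. Antibody-secreting-like cells were 2.51% of IPP (2.00 to 3.11) and 0.146% of NoPP. None of the 714 DUOD cells was of this class, which allows a share of up to 0.420% at 3 cells. Myeloid-like cells were 5.22% of NoPP and 2.01% of IPP. Unnamed clusters held 3.08, 0.920, 3.14 and 0.342% of the cells of DUOD, JEJ, IPP and NoPP. The B-like clusters held cells of both ileal libraries. These shares depended on the settings. The epithelial share was 66.9% in DUOD with the order-of-magnitude rule, 29.8% in DUOD and 42.0% in JEJ at 500 UMIs, and 3.92% in IPP and 11.5% in NoPP at a mitochondrial limit of 10%, so the order of both pairs turned. With each library clustered alone no NoPP cluster was named B-like.

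Among the epithelial cells, absorptive and secretory classes differed in share between regions. Enterocyte-like cells, the absorptive cells, were 78.0% of the 273 epithelial cells of DUOD (72.6 to 82.8), 61.6% of the 328 of JEJ (56.1 to 66.9), 65.6% of the 256 of IPP (59.5 to 71.4) and 26.8% of the 142 of NoPP (19.7 to 34.8). Goblet-like cells, which secrete mucus, were 1.10% in DUOD, 5.49% in JEJ, 17.2% in IPP (12.8 to 22.4) and 28.9% in NoPP (21.6 to 37.1). Hormone-making enteroendocrine-like cells were 16.8, 6.71, 13.3 and 30.3%. BEST4 enterocyte-like cells were 14.0% of JEJ (10.5 to 18.3) and 3.30, 3.13 and 7.04% of DUOD, IPP and NoPP. Crypt epithelial-like cells, which hold stem and dividing cells, were 12.2% of JEJ (8.86 to 16.2), 7.04% of NoPP and under 1% elsewhere. The crypt epithelial-like cluster had a higher mean log2 fold of Paneth markers (2.46) than of crypt markers (1.97). It took its name from 3 crypt markers among its leading genes, which also held the Paneth marker LYZ. No cluster met the rules for tuft, Paneth, M or Brunner gland cells. At 500 UMIs and 250 genes tuft-like clusters were named, with 20, 29, 20 and 31 cells or 8.20, 5.87, 7.81 and 18.0% of the epithelial cells of DUOD, JEJ, IPP and NoPP, so the absence depends on the UMI and gene limits. Filtered shares do not give tissue shares, since epithelium was released chemically and many barcodes exceeded the mitochondrial limit. The enterocyte-like shares depended on the settings. In DUOD they were 41.8% with each library clustered alone, in IPP and NoPP 29.2 and 12.0% at a mitochondrial limit of 10%, and at 500 UMIs JEJ (70.2%) lay above DUOD (67.2%). With shared barcodes kept, a setting chosen after seeing the data, they were 59.2% of the NoPP epithelial cells. The rule that names clusters was revised after the clusters had been seen, and its first version named 0.837% of the DUOD epithelial cells enterocyte-like and left 88.7% unnamed. It gave enteroendocrine-like shares of 5.02, 3.76, 8.64 and 10.9% in DUOD, JEJ, IPP and NoPP, so the order of DUOD and IPP turned.

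**Figure D1:**
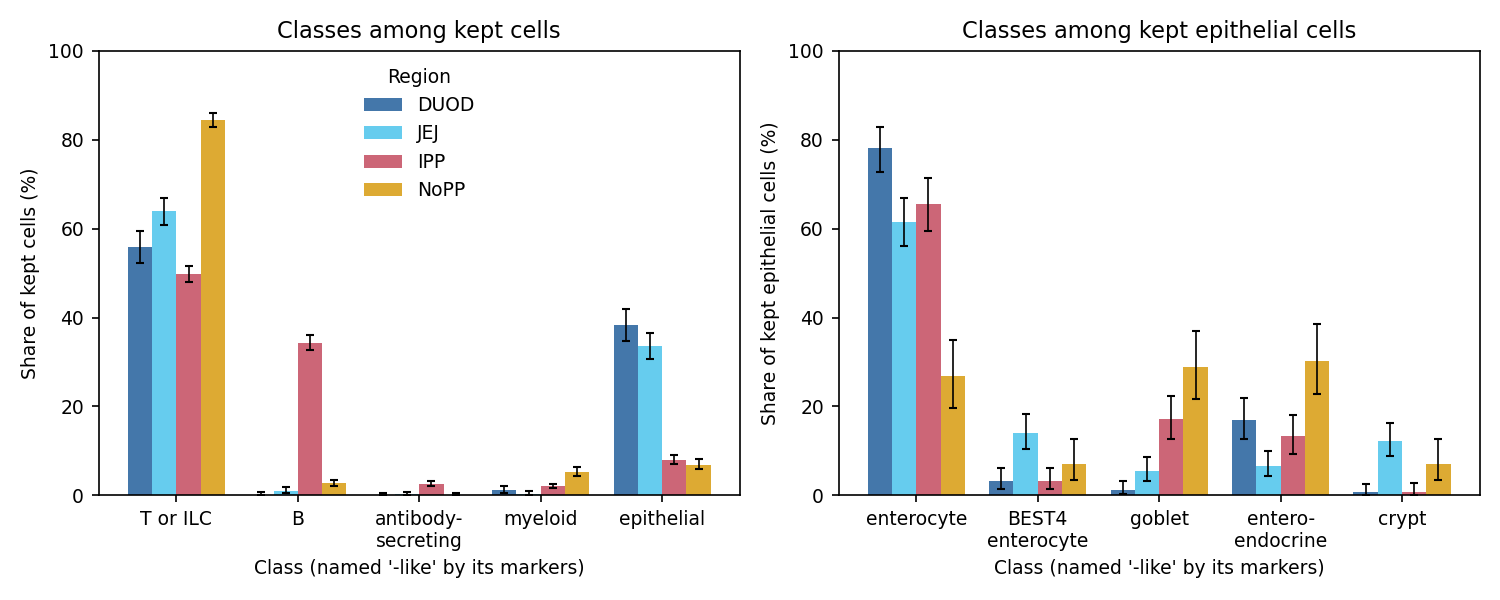
Share of kept cells by class (left, percent) and share of kept epithelial cells by class (right, percent) in the 4 regions; bars are shares and lines exact 95% Clopper-Pearson intervals. B-like cells reached 34.4% in IPP against 2.73% in NoPP, and epithelial cells 38.2% in DUOD against 6.93% in NoPP.

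The enterocyte-like cells numbered 213 in DUOD, 202 in JEJ, 168 in IPP and 38 in NoPP. Their median depth was 25788, 6023.5, 15679.5 and 15585.5 UMIs, and their median mitochondrial share was 13.1, 8.40, 17.2 and 13.7%. All but 1 of the DUOD cells lay in epithelial clusters 4, 7 and 9, and all but 1 of the JEJ cells in clusters 2 and 3. The ileal cells, but for 1, shared cluster 0 and the smaller cluster 12, which held 16 IPP and 11 NoPP cells and was also led by the immune genes CD74 and GNLY. Cluster 9, with 52 DUOD cells, was also led by the red cell gene HBB and the stress gene HMOX1 and by no enterocyte marker. Leaving its cells unnamed, a setting chosen after seeing the data, took the DUOD enterocyte-like share to 59.0%, with these cells still counted among the 273 epithelial cells. With the cluster out of the class, all 67 named genes past 2-fold against DUOD stayed past it in the same direction. This could hardly come out otherwise, because UMIs were summed over cells. Cluster 9 had a median of 2333.5 UMIs, against 32121 and 33966.5 in DUOD clusters 4 and 7. With 1 library per region, a cluster mostly of 1 library can reflect that library. Several genes compared here, among them TM4SF1, TMPRSS15, CA2, APOC3, SLC10A2 and FABP6, also led these clusters, and SI, FABP1, FABP2, FABP6, SLC51B, RBP2, APOA1 and APOC3 were among the markers that named enterocytes. FABP6 is the gene ENSSSCG00000017037, SI is ENSSSCG00000011735, TMPRSS15 is ENSSSCG00000012019 and TM4SF1 is ENSSSCG00000033018.

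The step from duodenum to jejunum asked how absorptive cells differ along the upper intestine. Genes for sugar digestion and uptake were far higher in JEJ. SI, the sucrase-isomaltase of the brush border, was at 1118 CPM in JEJ and 4.14 CPM in DUOD, 270-fold higher (interval 178 to 431). The glucose carrier SLC5A1 was 79.4-fold higher (62.3 to 103) and the maltase gene MGAM 25.6-fold (20.8 to 31.7). TMPRSS15, the enteropeptidase that activates trypsinogen, went the other way, at 2369 CPM in DUOD and 25.5 CPM in JEJ, 92.9-fold lower (75.6 to 115). TM4SF1 had 7849 UMIs in DUOD and 0 in JEJ, at least 1758-fold lower.

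Of 12 measured carbohydrate genes, 9 were at least 2-fold higher in JEJ and 0 lower, and the list's median lay at percentile 100 of random lists. Of 18 peptide digestion and amino acid genes, 12 were higher and 3 lower. Angiotensin-converting enzyme ACE was 205-fold higher on 2 DUOD UMIs (56.3 to 1705), the amino acid carrier SLC6A19 25.2-fold, the aminopeptidase ENPEP 8.14-fold and SLC7A7 7.77-fold. Of 19 lipid genes, 7 were higher and 1 lower. FABP2 was 9.67-fold higher (9.32 to 10.0), MTTP, which loads lipid onto chylomicrons, 3.54-fold and APOC3 2.66-fold. The retinol-binding protein gene RBP2 was 6.54-fold higher, and 2 of 8 vitamin genes were higher and 1 lower. Ion and water genes went both ways, 6 higher and 4 lower of 14. The water channel AQP8 was 30.9-fold higher, while carbonic anhydrase CA2 was 106-fold lower (76.5 to 150) and the bicarbonate carrier SLC4A4 6.27-fold lower.

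Mineral genes were split, with 3 of 13 higher and 4 lower. The iron genes SLC11A2, SLC40A1 and HEPH were lower in JEJ, by 6.06-fold (5.41 to 6.80), 2.63-fold and 3.17-fold. CYBRD1, a ferric reductase, was 8.28-fold higher and the phosphate carrier SLC34A3 16.6-fold. Of 13 xenobiotic genes, 1 was higher and 3 lower, with CYP2C49 6.39-fold lower. Of 15 dissociation and stress genes, 1 was higher and 3 lower. Defence genes split 2 and 2 of 6, with PIGR, the carrier of IgA, 11.2-fold higher and LYZ 69.8-fold lower, 29.4% of its UMIs in 1 cell. Transcription factors were 1 higher and 1 lower of 12, and KLF4 was 4.57-fold lower. The largest remaining ratios down included ANXA10, at 0 UMIs in JEJ and at least 291-fold lower, and TSPAN1, 288-fold lower. Of genes of other classes, goblet genes were 5 higher and 3 lower of 8, T effector genes 3 and 0 of 5, crypt stem genes 0 and 3 of 5 and hormone genes 0 and 3 of 3. Over all lists, 56 of 178 measured members were higher and 34 lower.

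The step from jejunum to ileum without patches asked what marks the distal absorptive cell. FABP6, which binds bile acids inside the cell, had the largest ratio. It was at 70235 CPM in NoPP (36055 UMIs) and 0.280 CPM in JEJ (1 UMI), with a ratio of at least 44975 at the lower end of its interval. SLC10A2, the bile acid carrier of the brush border, was 405-fold higher (184 to 1112). Its partners at the basal side, SLC51A and SLC51B, were 3.75-fold (3.19 to 4.41) and 2.16-fold (1.99 to 2.33) higher, and the bile acid receptor NR1H4 19.0-fold (14.6 to 25.1). Of the lipid genes, APOC3 was 37.7-fold lower (30.2 to 47.7) and FABP1 10.4-fold lower (9.86 to 11.0).

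Of 7 measured bile acid genes, 5 were higher and 2 lower. The lower ones included NR0B2, 27.8-fold lower on 1 NoPP UMI (4.93 to 1102). Of 19 peptide genes, 8 were higher and 3 lower. XPNPEP2 was 323-fold higher (147 to 888), the glutamate carrier SLC1A1 41.7-fold, NAALADL1 5.47-fold and ENPEP 4.58-fold. Vitamin genes were split 3 and 4 of 9. The vitamin B12 receptor genes CUBN and AMN were at least 197-fold and 3.33-fold higher, while RBP2 was 9.68-fold lower and BCO1, which splits carotene, at least 18.3-fold lower. Of 15 transcription factors, 5 were higher and 3 lower. HOXB7 was at least 62.6-fold higher, OSR2 410-fold on 1 JEJ UMI, with a lower limit of 70.8, and CDX2 2.28-fold, whereas GATA4 was 39.7-fold lower on 1 NoPP UMI (7.07 to 1574) and ONECUT2 at least 25.1-fold lower. The sulfate carrier SLC13A1 was 2579-fold higher on 1 JEJ UMI, with a lower limit of 460, and CPO at least 368-fold higher.

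Of 19 lipid genes, 1 was higher and 9 lower, among them APOA1, 5.76-fold lower (5.54 to 5.99), and APOA4, 3.78-fold lower. Of 13 mineral genes, 1 was higher and 7 lower. The calcium-binding S100G was 17.4-fold lower (16.4 to 18.3), the calcium pump ATP2B1 10.3-fold lower and the iron exporter SLC40A1 32.7-fold lower on 3 NoPP UMIs (11.1 to 159). The metallothionein MT1A was the higher one, by 2.23-fold. Of 14 xenobiotic genes, 1 was higher and 8 lower, with GSTA2 10.2-fold lower and SULT1E1 1390-fold higher on 1 JEJ UMI, with a lower limit of 247. The carbohydrate list was 1 higher and 5 lower of 12, and trehalase TREH was at least 31.2-fold lower. All 6 of the 14 interferon genes past 2-fold were lower, with ISG15 11.0-fold lower. Of 8 T effector genes 6 were higher in the NoPP enterocyte-like cells and 0 lower, with at least 50% of the GNLY, GZMA and GZMB UMIs in 1 cell. Goblet genes were 0 higher and 6 lower of 7 and hormone genes 3 and 0 of 3. The median log2 ratio of genes with at least 50 CPM was -0.16, and leaving out the mitochondrial, ribosomal and 10 highest genes shifted all ratios by 0.21. SLC51B and ENPEP turned lower at a mitochondrial limit of 10%, at log2 ratios of -0.19 and -1.24. Few NoPP cells were left there, since enterocyte-like cells were 12.0% of 83 epithelial cells.

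**Figure D2:**
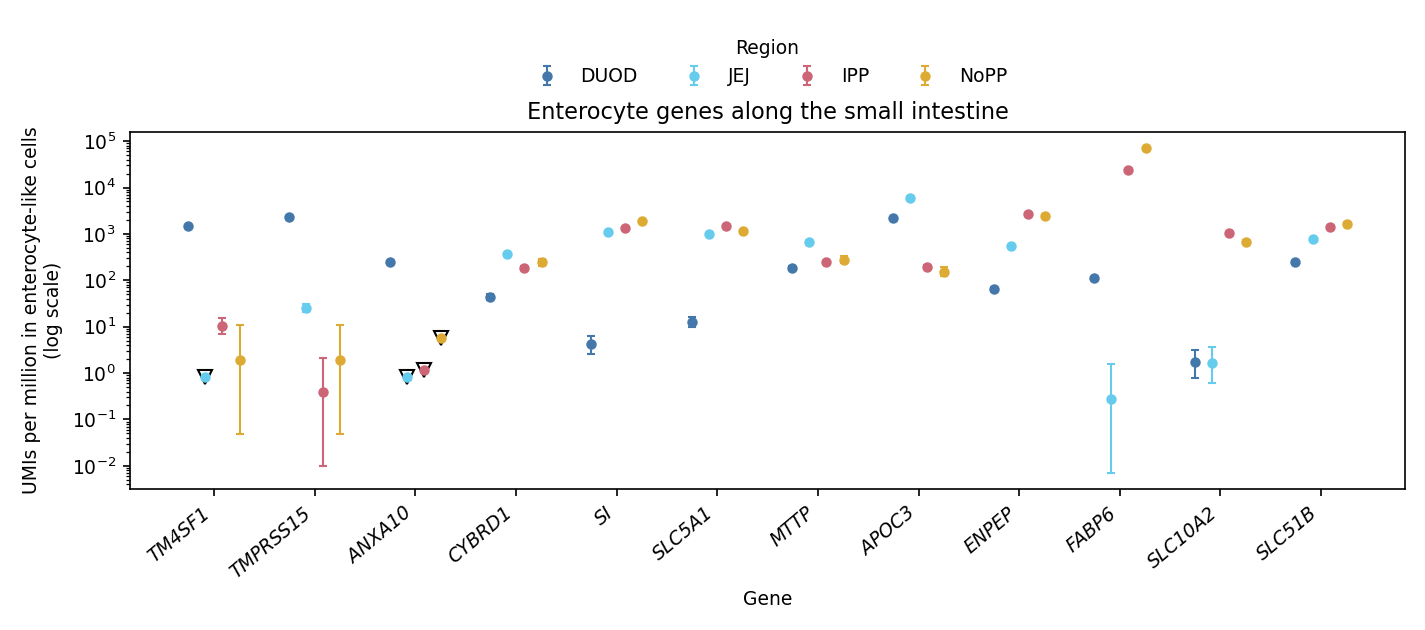
Level of 12 genes in enterocyte-like cells (CPM, log scale) in the 4 regions, with exact 95% Poisson intervals; triangles stand for 0 UMIs, drawn at the floor of 3 UMIs. FABP6 reached 70235 CPM in NoPP and 24393 CPM in IPP, while SI stood at 1118 CPM in JEJ and 4.14 CPM in DUOD.

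Between both ends, NoPP against DUOD, 69 of 192 list members were higher and 63 lower, and 59 and 66 without each gene's highest cell, a setting chosen after seeing the data. That setting tends to take a larger part from NoPP, which had fewer cells. SI was 461-fold higher in NoPP (303 to 739) and SLC10A2 402-fold. XPNPEP2 was 962-fold higher on 3 DUOD UMIs (326 to 4694). FABP6 was 633-fold higher (584 to 688), with 1 cell holding nearly all of the DUOD UMIs. TMPRSS15 was 1216-fold lower on 1 NoPP UMI, with a lower limit of 218, and CA2 at least 187-fold lower. Peptide genes were 14 higher and 2 lower of 18, ion and water genes 11 and 2 of 17, bile acid genes 5 and 2 of 7, and carbohydrate genes 6 and 2 of 12. Of genes of other classes, 6 of 7 T effector genes were higher and 0 lower, and 0 of 7 goblet genes higher and 6 lower. Mineral genes were 2 higher and 8 lower of 13, with SLC40A1 and SLC11A2 86.0-fold and 98.2-fold lower on 3 NoPP UMIs each (29.4 to 418 and 33.6 to 476). The transcription factors OSR2 and CDX2 were 102-fold and 3.69-fold higher. PDX1, the duodenal and pancreatic regulator, was at least 8.57-fold lower and GATA4 33.8-fold lower on 1 NoPP UMI (6.03 to 1340). The median log2 ratio of genes with at least 50 CPM was -0.11, and leaving out the highest genes shifted the ratios by 0.24. Barcodes rich in DUOD were found again in NoPP and were left out where they had at least 10 times as many UMIs in DUOD.

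**Figure D3:**
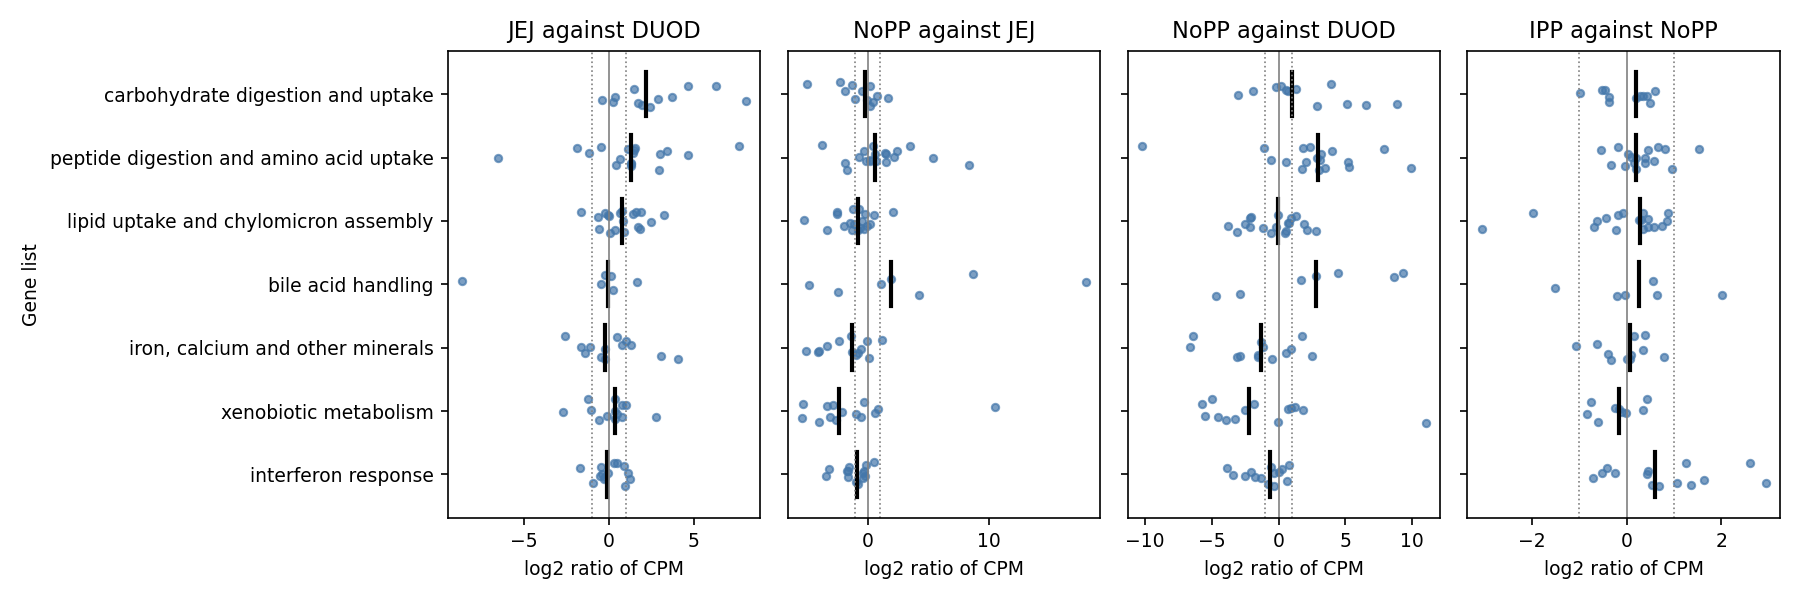
Log2 ratio of each measured member of 7 gene lists in enterocyte-like cells for the 4 comparisons of regions; points are genes, black bars medians and dotted lines a 2-fold difference each way. Of the carbohydrate genes, 9 of 12 lay above the upper line for JEJ against DUOD, and of the mineral genes 7 of 13 lay below the lower line for NoPP against JEJ.

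Ileum with and without patches was compared to ask whether absorptive cells near lymphoid tissue differ. Between the enterocyte-like cells of both ileal libraries, 23 of 170 list members were higher in IPP and 14 lower. Interferon genes were higher in IPP, 6 of 14 and 0 lower, at percentile 100 of random lists. ISG15 was 7.69-fold higher (4.00 to 16.9), IRF1 3.12-fold (2.08 to 4.89) and IFI6 2.39-fold (1.79 to 3.25). Interferon genes, ISG15 among them, were also lower in NoPP than in JEJ, as given above. A low level in NoPP is thus not particular to this pair, and no effect of patches can be read from it. FABP6 was 2.88-fold lower in IPP (2.84 to 2.92). The guanylin genes GUCA2A and GUCA2B, which drive fluid secretion, were 2.66-fold and 2.53-fold higher, the tight junction gene CLDN4 2.75-fold and TSPAN1 4.79-fold. KRT8 was 3.25-fold lower and PPP1R1B 9.40-fold lower. Of 11 carbohydrate genes 0 passed 2-fold either way, of 17 peptide genes 1 was higher, and of 18 lipid genes 2 were lower. Of 8 goblet genes 6 were higher, but for TFF3, SPINK4 and REG4 at least 50% of the IPP UMIs sat in 1 cell. The balance of all list members turned with the setting: 12 were higher and 21 lower at 500 UMIs, 15 and 22 with the order-of-magnitude rule, 20 and 30 with each library clustered alone, 21 and 23 at a mitochondrial limit of 40%, 27 and 32 with no list minimum, and 21 and 27 with the mean of the cells' CPM. Of settings chosen after seeing the data, keeping shared barcodes gave 14 and 46 and leaving out each gene's highest cell 25 and 3. Leaving out the highest cell tends to take a larger part from the 38 NoPP than from the 168 IPP cells. The fall in genes lower in IPP is therefore partly built in. At a mitochondrial limit of 10% GUCA2B turned lower and OTC, ADH5 and EPHX1 turned higher. Few cells were left at that limit, with enterocyte-like cells 29.2% of 65 IPP and 12.0% of 83 NoPP epithelial cells.

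Crypt epithelial-like cells could be compared between NoPP (10 cells) and JEJ (40 cells), and lay in 1 cluster. They asked whether the regional differences precede differentiation. Of 192 list members 68 were higher in NoPP and 48 lower, and of 161 without each gene's highest cell, a setting chosen after seeing the data, 43 and 38. That setting tends to take a larger part from NoPP, which had fewer cells. Of 18 transcription factors 8 were higher and 2 lower. OSR2 and HOXB7 were at least 12.0-fold and 11.1-fold higher and ONECUT2 at least 8.19-fold lower, the directions seen in the enterocyte-like cells. SPAI-2, a protease and sodium pump inhibitor, had 2962 UMIs in NoPP and 0 in JEJ, at least 2732-fold higher. Genes lower in NoPP included S100G, 72.3-fold (47.2 to 117), SPINK1 44.9-fold and GSTA2 308-fold on 2 NoPP UMIs (85.2 to 2548). Of 18 lipid genes 2 were higher and 11 lower, of 12 mineral genes 0 and 6, and of 10 xenobiotic genes 0 and 6. Lipid genes were also lower in NoPP than in JEJ in T or innate lymphoid-like cells, which should lack them. The lipid count therefore cannot settle whether the differences precede differentiation. Peptide genes were 4 higher and 4 lower of 13, ion and water genes 6 and 5 of 13, goblet genes 6 and 2 of 10, and T effector genes 5 and 0 of 8. Of 21 proliferation genes 12 were higher and 0 lower, among them BIRC5, 4.01-fold (2.19 to 7.48). For CENPF and TOP2A over 50% of the NoPP UMIs sat in 1 cell. Of 10 crypt stem genes 5 were higher and 1 lower, with CD44 52.6-fold higher on 1 JEJ UMI (8.36 to 2184). Dissociation and stress genes were 6 higher and 2 lower of 17. Median depth was 13226 UMIs in NoPP and 3240.5 in JEJ, the median mitochondrial share 8.15 and 2.48%, and the median log2 ratio of genes with at least 50 CPM was 0.11.

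Goblet-like cells of IPP (44) and NoPP (41), from 1 cluster, had like levels of their main products. TFF3, the trefoil peptide of mucus, was at 107963 CPM in IPP and 112537 CPM in NoPP, and 0 of 11 goblet genes passed 2-fold. Peptide digestion genes were higher in IPP, 11 of 18 against 1 lower, with NAALADL1 5.35-fold (3.79 to 7.75) and MEP1B 3.14-fold. Bile acid genes were 5 higher and 0 lower of 7. These and the lipid genes are genes of enterocytes, and other lists of other classes moved too, with B follicle genes 2 higher and 0 lower of 5, T effector genes 2 and 0 of 8 and MHC class II genes 2 and 1 of 3. The lipid genes FABP2, FABP1 and APOA1 were 8.97-fold, 3.58-fold and 3.86-fold higher, with 34.5% of the FABP2 UMIs and 31.9% of the APOA1 UMIs in 1 cell. In NoPP the interferon list was higher, with 8 of 15 genes lower in IPP and 1 higher, the opposite order to the enterocyte-like cells, a difference between classes that was not tested. ISG15 was 3.12-fold lower in IPP (2.07 to 4.80), while IRF1 was 2.15-fold higher. Of 8 defence genes 4 were lower. ITLN2, an intelectin that binds microbial sugars, was 937-fold lower on 1 IPP UMI, with a lower limit of 168. Its 660 NoPP UMIs came from 14.6% of the cells, and 1 cell held 40.2% of all its UMIs. RETNLB was 42.6-fold lower on 3 IPP UMIs (14.1 to 210). Over all lists 43 of 186 members were higher in IPP and 22 lower, but 26 and 42 at 500 UMIs, 32 and 42 with doublets kept and 22 and 32 at a mitochondrial limit of 40%. The peptide genes were 3 higher and 1 lower at 500 UMIs, 7 and 1 with doublets kept and 6 and 2 at 40%.

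Enteroendocrine-like cells of NoPP (43) and DUOD (46) showed different hormones. GCG, the gene of GLP-1, had 14676 UMIs in NoPP and 0 in DUOD, at least 9266-fold higher. PYY, a hormone that slows the gut, was 32.4-fold higher (30.7 to 34.3) and NTS, neurotensin, 31122-fold higher on 1 DUOD UMI, with a lower limit of 5585 and 46.9% of its UMIs in 1 cell. CCK, which releases bile and pancreatic juice, was 1437-fold lower (1029 to 2076), secretin SCT 376-fold lower (210 to 754) and ghrelin GHRL 34.2-fold lower (31.0 to 38.0). Motilin MLN had 23976 UMIs in DUOD and 0 in NoPP, at least 4219-fold lower, and somatostatin SST was 2.49-fold lower (2.46 to 2.51). Of 18 hormone list members, 8 were higher and 7 lower. GCG is the gene ENSSSCG00000015895. The hormones were among the markers that named the class, and its clusters 6, 10 and 11 held 40, 6 and 0 DUOD cells and 14, 12 and 17 NoPP cells.

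Of 19 transcription factors, 12 were higher in NoPP and 2 lower. HOXB9 and HOXB8 were at least 65.0-fold and 64.4-fold higher, and ONECUT2 was 4.08-fold lower (2.38 to 7.53). Genes of other classes also moved, with T effector genes 6 higher and 0 lower of 9, carbohydrate genes 6 and 0 of 9, bile acid genes 5 and 0 of 5 and peptide genes 10 and 2 of 15. Dissociation and stress genes were 11 higher and 1 lower of 17, with FOS 5.78-fold and NR4A1 6.67-fold higher. TTR was at least 223-fold lower and GIP 44.3-fold lower, with over 50% of the NoPP GIP UMIs in 1 cell. SST made up 23.1% of the DUOD and 9.27% of the NoPP UMIs of the class, the median log2 ratio of genes with at least 50 CPM was 0.49, and leaving out the highest genes shifted the ratios by -0.38. Over all lists 91 of 182 members were higher and 28 lower, and 77 higher and 39 lower without mitochondrial, ribosomal and the 10 highest genes.

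Between DUOD and NoPP, the share of cells with a UMI went the same way as the CPM for GCG, CCK, MLN and NTS. It went against the CPM for GAST (32.6% of DUOD and 46.5% of NoPP cells, 34.8-fold lower in CPM), CHGA (100 and 88.4%, 2.46-fold higher) and PCSK1 (91.3 and 88.4%, 3.55-fold higher), so no order is read from their shares. These are shares of cells in which a UMI was seen at this depth, and their limits do not bound the share of cells that express the gene. GCG was seen in 0 of the 46 DUOD cells, which allows up to 6.52%, in 4.55% of JEJ, 35.3% of IPP and 60.5% of NoPP cells. T or innate lymphoid-like cells, which should lack it, had a UMI in 0, 0.160, 6.30 and 10.1%. CCK was seen in 52.2, 31.8, 14.7 and 20.9% of the DUOD, JEJ, IPP and NoPP cells, against 9.52, 1.60, 0.252 and 0.520% of T or innate lymphoid-like cells. MLN was seen in 41.3% of DUOD and 13.6% of JEJ cells and in 0 of the ileal ones, which allows up to 8.82% in IPP and 6.98% in NoPP. The T or innate lymphoid-like shares of MLN were 5.76, 3.84, 0.126 and 0.116%. NTS was seen in 48.8% of NoPP cells and in 32.8% of NoPP T or innate lymphoid-like cells. Median depth was 17027, 13307, 12401 and 11279 UMIs against 2918, 3599, 3595 and 3522 UMIs in the T or innate lymphoid-like cells. Thinned to 1000 UMIs, GCG was seen in 0, 4.55, 26.5 and 39.5%, CCK in 32.6, 22.7, 8.82 and 4.65% and NTS in 0, 18.2, 11.8 and 14.0%, with NTS in 13.6% of NoPP T or innate lymphoid-like cells.

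**Figure D4:**
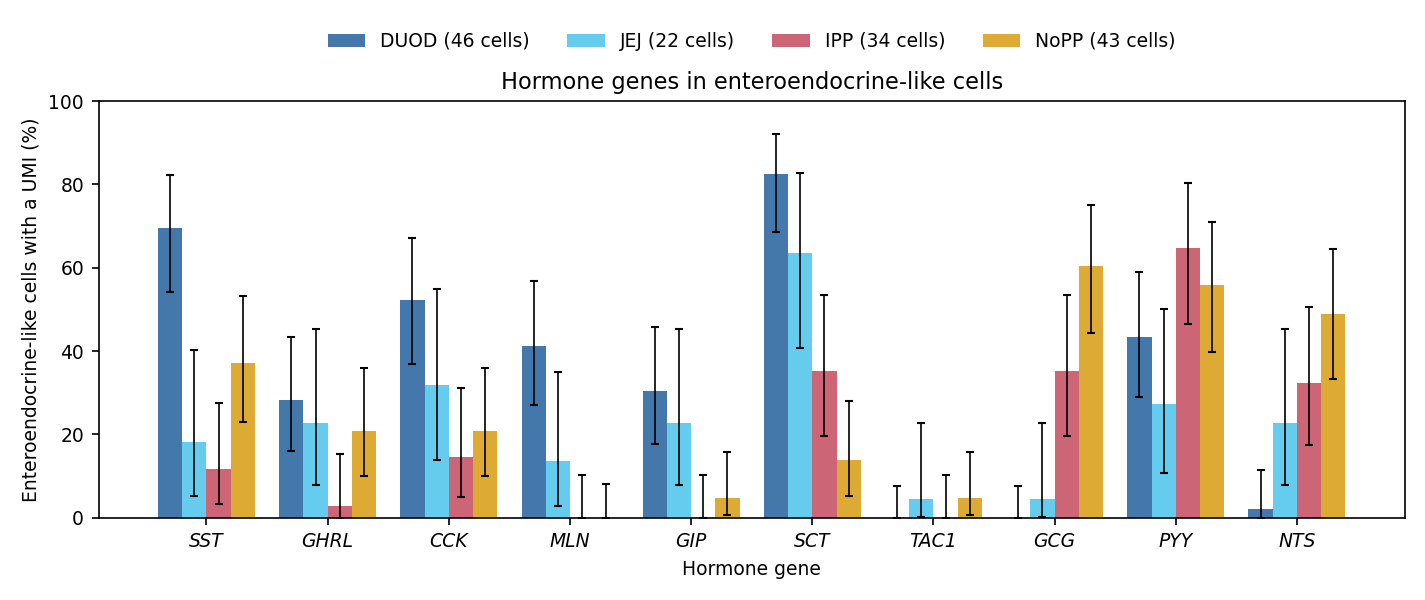
Percent of enteroendocrine-like cells with at least 1 UMI of 10 hormone genes in the 4 regions, without correction for free RNA or depth. CCK was seen in 52.2% of DUOD cells and 20.9% of NoPP cells, and GCG stood at 0% in DUOD and 60.5% in NoPP.

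In IPP (34 cells) against NoPP, GCG was 4.79-fold lower (4.61 to 4.98), with 37.2% of its IPP UMIs in 1 cell. SST and GHRL were 5.16-fold (5.04 to 5.29) and 29.6-fold lower (17.1 to 56.2), but all but 3 of the 8400 SST UMIs and all 13 GHRL UMIs of IPP came from 1 cell. Cluster 6, led by SST and GHRL among others, held 1 IPP and 14 NoPP cells, and clusters 10 and 11 held 21 and 12 IPP against 12 and 17 NoPP cells, so the libraries are compared over different mixes of cells. NTS was 3.03-fold higher, 36.7% of its UMIs in 1 cell. The pan-endocrine marker CHGA was at 5942 and 6138 CPM. Hormone genes were 4 higher and 5 lower of 18, transcription factors 0 higher and 8 lower of 18, dissociation and stress genes 0 and 5 of 16, T effector genes 0 and 8 of 9, MHC class II genes 3 and 0 of 3, B follicle genes 2 and 0 of 3, and goblet genes 5 and 2 of 10. Goblet and B follicle genes belong to other classes. The synaptic gene SNAP25 was at 383 CPM in IPP and 109 CPM in NoPP. The median log2 ratio of genes with at least 50 CPM was -0.10. All list members gave 29 higher and 47 lower, and 41 higher and 38 lower with the mean of the cells' CPM. At a mitochondrial limit of 40% NTS turned lower, at a log2 ratio of -8.90, and at 2000 UMIs TFF3 turned lower, from a ratio of 3.88, to a log2 ratio of -0.40.

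In T or innate lymphoid-like cells the chemokine gene CCL5 was at 18771, 22439, 17372 and 18776 CPM in DUOD, JEJ, IPP and NoPP. From DUOD (399 cells) to JEJ (625), the killer proteases GZMA (ENSSSCG00000016902) and GZMB were 2.39-fold (2.29 to 2.49) and 1.87-fold higher, and the other GZMA gene (ENSSSCG00000016903) 2.08-fold. KLRB1 was 2.28-fold higher and GLIPR2 2.55-fold lower. Of 24 T effector genes 2 were higher and 1 lower, and the list's median lay at percentile 99.99. Its members GNLY, GZMA and GZMB were also markers that named the class and leading genes of cluster 0. That cluster held 17.0% of the class in DUOD and 31.0% in JEJ. Over all lists 14 of 147 members were higher and 15 lower, against 14 and 23 without the highest genes, 5 and 25 with free RNA subtracted, 13 and 40 with each library clustered alone and 15 and 9 without each gene's highest cell, a setting chosen after seeing the data. From JEJ to NoPP (1731 cells), granulysin GNLY was 2.42-fold higher, at 4456 and 1841 CPM, and LTB 2.39-fold lower. With IPP in place of NoPP, a setting chosen after seeing the data, LTB turned higher than in JEJ, at a log2 ratio of 0.35. The 4 measured MHC class II genes stayed within 2-fold, with SLA-DQB1 1.78-fold higher. TAC3, the neurokinin B gene (ENSSSCG00000000418), was 883-fold lower on 1 NoPP UMI (157 to 34967). Against DUOD, GNLY was 3.26-fold higher (3.11 to 3.42) in NoPP, KLRK1 2.02-fold higher, IL7R 2.28-fold lower and LTB 4.05-fold lower. Epithelial genes differed in these cells too, which should lack them, and 8 of 13 lipid genes were lower in NoPP than in JEJ and 0 higher, with FABP1 at 9.06 and 289 CPM.

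In IPP (1587 cells) against NoPP, CCR7, the lymph node homing receptor, was 6.16-fold higher (4.70 to 8.19) in the T or innate lymphoid-like cells, LTB 3.05-fold (2.75 to 3.38) and IL7R 1.67-fold. CD8A was 1.53-fold lower. Of 15 interferon genes 2 were higher and 0 lower, with IFI6 2.70-fold. Of 19 proliferation genes 0 were higher and 4 lower, with CENPF 2.17-fold (1.86 to 2.53) and TPX2 2.51-fold lower. Of 9 B follicle genes, a list that also holds CCR7 and LTB, 3 were higher. CCR7 was also a leading gene of B-like cluster 3, and B-like cells made up 34.4% of IPP and 2.73% of NoPP. These genes are therefore not particular to T or innate lymphoid-like cells. Across the 4 comparisons 29, 36, 49 and 23 list members passed 2-fold. With free RNA subtracted NoPP against JEJ gave 4 higher and 6 lower in place of 12 and 24, with each library clustered alone 29 and 24, and the order-of-magnitude rule took NoPP against DUOD from 15 and 34 to 33 and 55. Each cluster of the class held cells of every region, in different shares. Cluster 0, led by GNLY, held 17.0, 31.0, 32.7 and 31.1% of the class in DUOD, JEJ, IPP and NoPP. Cluster 8, whose leading genes include CCR7, held 7.31% in IPP and 3.18% in NoPP, and dividing cluster 11 held 2.96 and 4.45%, so the mix of clusters differed too. Cluster 14 was also led by HBB.

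B-like cells of IPP (1095) and NoPP (56) differed in genes of the dissociation and stress list, which also respond to handling. With each library clustered alone NoPP held 0 B-like cells, which left no comparison. FOS was 2.65-fold lower in IPP (2.25 to 3.10), JUN 2.68-fold, CD69 3.03-fold and EGR1 4.12-fold, and 5 of 14 genes of that list were lower and 0 higher. CD79A, part of the B cell receptor, was 2.97-fold higher (1.69 to 5.77) and POU2AF1, a B cell coactivator, 2.33-fold. Of 18 B follicle genes 2 were higher and 1 lower, while MS4A1, the CD20 gene, was at 756 and 1049 CPM. Of 21 proliferation genes 1 was higher, and 0 of 6 MHC class II genes passed 2-fold. Of 129 list members 15 were higher and 14 lower, against 14 and 20 with the mean of the cells' CPM, 13 and 25 at a mitochondrial limit of 10%, 3 and 10 with free RNA subtracted, and 21 and 6 without each gene's highest cell, a setting chosen after seeing the data. The last setting tends to take a larger part from the smaller NoPP class, so its shift is partly built in.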

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

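The excess of shared barcodes over chance and the mitochondrial share of barcodes above the limit in JEJ, IPP and NoPP were tests chosen only after the result was seen.

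Barcodes outside the comparisons carried RNA: of those with at least 1000 UMIs, 92.1% in DUOD, 88.6% in JEJ, 71.7% in IPP and 73.9% in NoPP had more than 25% mitochondrial UMIs. By their other UMIs a median of 95.9% per library resembled the profile of free RNA most, but in JEJ, IPP and NoPP free RNA alone is argued against by a median mitochondrial share at least 31.2 points above it. The medians were 72.9, 73.1, 75.6 and 72.6% in DUOD, JEJ, IPP and NoPP, against 68.8, 41.9, 36.7 and 38.6% in free RNA, which leaves DUOD open. Among those resembling cells, the epithelial share was 79.6, 41.1, 51.4 and 24.6% against 38.2, 33.5, 8.03 and 6.93% of the kept cells, higher beyond the interval in 3 of 4 libraries but not in JEJ (33.4 to 49.2), so the limit may take out epithelial cells more than others, which cannot be told from these data. Damaged cells that kept mitochondria and lost other RNA, and a difference between the regions themselves, were not tested and stay open.

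In NoPP, 239 barcodes with at least 1000 UMIs had at least 10 times as many UMIs in DUOD, which singles out this pair of libraries. Chance is argued against, since 367 barcodes had at least 1000 UMIs in both libraries and 12.6 were expected, and the 239 alone were 19.0 times that (7 of the others remain among the final NoPP cells). Free duodenal RNA is argued against, because 62.8% (61.5 to 64.1) of the NoPP UMIs of TM4SF1, TMPRSS15, ANXA10 and CSTA sat in barcodes rich in DUOD, against 7.81% of the UMIs of all genes. Molecules of the DUOD library counted in NoPP may be the source, as DUOD barcodes gave 4.46% of their UMIs again in NoPP, and T or innate lymphoid-like and enterocyte-like barcodes did so with medians a factor of 1.07 apart. This stays open, since the highest other pair of libraries reached 0.634%, short of the 10-fold distance set beforehand.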

How the results depend on the processing

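Keeping shared barcodes, the other ileal library in place of NoPP, leaving out each gene's highest cell, leaving out the epithelial cluster led by a red cell marker and cells of at least 10000 UMIs were chosen after seeing the data; the other settings were planned. No paired analysis was possible because the 4 titles of a region share 1 matrix and no barcode maps to a title, and for the same reason leaving out each replicate was not run. Depth limits ratios of genes near 3 UMIs and classes of few cells, and intervals do not cover differences between pigs or libraries. Leaving out each gene's highest cell kept the class totals and tends to lower the library with fewer cells more.

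Of 3724 values of named genes under planned settings, 3093 stayed inside their interval, 622 moved and 9 reversed. Under added settings these were 712, 202 and 1 of 915. A reversal was counted only for genes at least 2-fold apart in the main setting. Smaller ratios that changed direction, if any, were counted as stayed or moved. Of the named genes past 2-fold that could be compared, 77.9% (162 of 208) stayed past it in the same direction at a mitochondrial limit of 10%, 92.0% (242 of 263) with the mean of the cells' CPM and 100% (263 of 263) at a resolution of 2. The other settings lay between these last values or kept 103 of 113 (other ileal library). Counts for single lists stayed in 4163 of 4998 planned cases. For counts, stayed means equal to the main count or within a fixed factor of it, so smaller changes are included. Values from cells thinned to 1000 UMIs stayed in 27 of 92. The thinned values include median genes per cell, such as 3899 and, thinned, 476 in DUOD enterocyte-like cells. These had no interval and must fall with depth, so they could only move. Some settings left too few cells for a comparison and gave no value, such as crypt epithelial-like cells at a limit of 10%. The cause was not tested for any value that follows, except that list minimums change how many genes are counted.

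Epithelial shares of kept cells were 29.8% in DUOD and 42.0% in JEJ at 500 UMIs, 66.9, 37.4 and 10.3% in DUOD, JEJ and IPP with the order-of-magnitude rule, 50% in DUOD, 3.92% in IPP and 11.5% in NoPP at a mitochondrial limit of 10%, 46.5, 41.2, 10.2 and 9.41% in DUOD, JEJ, IPP and NoPP at 40%, and 12.0% in NoPP with shared barcodes kept. B-like shares of IPP were 32.3% at 500 UMIs, 38.8% at 2000, 42.9% with the order-of-magnitude rule, 52.0% at a limit of 10% and 36.9% at 0.5 of the resolution. In NoPP they were 4.70% at a limit of 10% and 0% when each library was clustered alone.

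Enterocyte-like shares of epithelial cells were 67.2, 70.2, 59.4 and 18.0% in DUOD, JEJ, IPP and NoPP at 500 UMIs, 68.6% in JEJ with the order-of-magnitude rule, 63.3, 29.2 and 12.0% in DUOD, IPP and NoPP at a limit of 10%, and 83.9% in DUOD and 35.0% in NoPP at 40%. They were 59.7% in DUOD at 0.5 of the resolution, 41.8% in DUOD and 45% in IPP with each library alone, and 59.2% in NoPP with shared barcodes kept. With the cluster led by a red cell marker unnamed but still counted as epithelial, they were 59.0% in DUOD. Under the first of 3 earlier versions of the naming rule, also run after seeing the data, they were 0.837, 62.4, 62.6 and 24.5% in DUOD, JEJ, IPP and NoPP. The later 2 versions left them unchanged. Enteroendocrine-like shares under the first version were 5.02, 3.76, 8.64 and 10.9%. Tuft-like cells were 8.20, 5.87, 7.81 and 18.0% of the epithelial cells of DUOD, JEJ, IPP and NoPP at 500 UMIs.

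Counts of list members past 2-fold in enterocyte-like cells moved as follows. For JEJ against DUOD 22 were lower at a list minimum of 50 CPM and 52 with none. For NoPP against JEJ 31 were higher and 41 lower at a limit of 10%, and 73 were higher with no list minimum. For NoPP against DUOD 39 were lower at a limit of 10%. For IPP against NoPP 12 were higher at 500 UMIs, 15 with the order-of-magnitude rule, 37 at a limit of 10%, 14 with shared barcodes kept and 13 at 50 CPM. There 22 were lower with the order-of-magnitude rule, 23 at a limit of 40%, 30 with each library alone, 46 with shared barcodes kept, 27 with the mean of the cells' CPM, 3 without each gene's highest cell, 7 at 50 CPM and 32 with no minimum.

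In other classes, the members past 2-fold either way at a list minimum of 50 CPM were 69 in crypt epithelial-like, 34 in goblet-like, and 71 and 34 in enteroendocrine-like cells (NoPP against DUOD, IPP against NoPP). In T or innate lymphoid-like cells they were 13 for JEJ against DUOD, 15 for NoPP against JEJ, 17 for NoPP against DUOD and 8 for IPP against NoPP, and 12 in B-like cells. With no minimum the same T or innate lymphoid-like comparisons gave 65, 105, 110 and 71, and B-like cells 66. In T or innate lymphoid-like cells the order-of-magnitude rule gave 60 for JEJ against DUOD and 88 for NoPP against DUOD, a limit of 10% gave 56 for JEJ against DUOD and 36 for IPP against NoPP, and clustering alone gave 53 for JEJ against DUOD. With free RNA subtracted NoPP against JEJ gave 10 and B-like cells 13.

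The reversals of genes that were at least 2-fold apart in the main setting were as follows, as log2 ratios. A limit of 10% left few ileal enterocyte-like cells, 29.2% of 65 IPP and 12.0% of 83 NoPP epithelial cells. At this limit SLC51B was -0.19 and ENPEP -1.24 for NoPP against JEJ. For IPP against NoPP, GUCA2B was -0.73, OTC 0.56, ADH5 1.15 and EPHX1 1.43 in enterocyte-like cells, and MT1A -0.024 in B-like cells. In enteroendocrine-like cells, IPP against NoPP, NTS was -8.90 at a limit of 40% and TFF3 -0.40 at 2000 UMIs. With the other ileal library LTB was 0.35 for ileum against JEJ in T or innate lymphoid-like cells.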

Other observations

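All tests on TAC3 in this part were chosen after the result was seen.

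Classes were also set against the other epithelial cells of their own region. Cells had been grouped by expression, so these genes describe the groups and test nothing, and the leading genes of the clusters are left out. In JEJ the 46 BEST4 enterocyte-like cells held GP2, a receptor for bacteria, 4825-fold higher than the other epithelial cells on 3 UMIs in these (1645 to 23450). GP2 was also on the marker list for M cells, a class that no cluster was given. RAMP1, a coreceptor for the peptide CGRP, and the regulator MEIS1 were higher on 1 UMI each in the other cells, with lower limits of 338 and 206. The JEJ crypt epithelial-like cells held the complement gene C5 70.8-fold higher (35.3 to 161).

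In the ileum, goblet-like cells held TCN1, which binds vitamin B12, higher on 1 UMI in the other cells of each library, with lower limits of 465 in IPP and 133 in NoPP. In DUOD, enteroendocrine-like cells held the pancreatic polypeptide gene PPY at least 1191-fold higher. DUOD enterocyte-like cells held the growth factor EREG higher on 1 UMI in the other epithelial cells, with a lower limit of 37.0, and the calcium channel TRPV5 69.9-fold higher (27.2 to 257).

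Cluster 9 of the T or innate lymphoid-like cells was led by TAC3 and IL22, and its TAC3 level differed between libraries. It held TAC3 in 33 of 37 DUOD, 38 of 48 JEJ, 27 of 63 IPP and 1 of 37 NoPP cells, at 1957, 1171, 846 and 5.31 CPM. IL22, the cytokine that acts on epithelium, was at 245, 164, 1330 and 1369 CPM and TIMP1 at 842, 777, 4655 and 5921 CPM.

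TAC3 in the other T or innate lymphoid-like clusters reached at most 0.000414 of its level in this cluster. The cluster was picked because TAC3 led it, so a low level elsewhere follows in part from that choice. It is therefore no separate evidence against free RNA in the other libraries. Too few UMIs in NoPP is argued against, since 160 UMIs were expected at the IPP level and 1 was seen, which allows up to 5.57. Other cells in the NoPP part of the cluster stays open. For its 9 other leading genes the median ratio of NoPP to IPP was 0.938 (lowest gene 0.482, highest gene 1.67). This ratio cannot test the explanation in cells that were grouped by such genes. A difference between the sites, the animals or a variant that hides the gene stays open and untested.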
